A study of Danio rerio with 6 samples.

How the data were processed

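Single-cell RNA sequencing was performed on cells sorted for GFP from zebrafish embryos of the Tg(kdrl:EGFP) line at 30 hours post-fertilization (hpf). In this line the promoter of kdrl, a VEGF receptor gene of the endothelium, drives GFP. The embryos were wild-type for ezh1 (WT), heterozygous (HET) or homozygous mutant (KO). Ezh1 is a catalytic subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3. Per the labels' protocols, pools of embryos were dissociated with Liberase, sorted, and loaded over 2 lanes of a 10x Genomics 3' v2 chip per genotype as technical replicates, which gives 6 libraries. The number of pools and clutches behind a genotype is not given, so p-values measured the spread between lanes, and every difference is one between the pools. The labels do not say what the mutation is.

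The deposited files hold raw UMI counts per gene and cell barcode with 1 matrix per lane, per the file headers and the values, which were whole numbers. Cell Ranger 2.1, R 3.5, Seurat 3.2 and the build GRCz11 are named in the submitters' processing notes, with no role or setting stated. All later steps were computed from these counts with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).

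Of 11151 barcodes, 18 with fewer than 500 genes or more than 10% mitochondrial UMIs were left out. The 5% of barcodes with the highest Scrublet scores in each lane were then removed as likely doublets, because the labels put the doublet rate below 5% and the tool's own threshold called at most 17 in a lane; 10574 cells remained. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1. A cluster of at least 20 cells took the name of a cell class when at least 3 markers of that class were at least 2-fold higher in it and found in at least 20% of its cells. At least 2 markers had to be among its 30 leading genes, and the class had to have over 2 times as many markers as the next. These naming thresholds were set after the clusters had been seen, and the cells left without a name are given as a share of their own. The marker lists covered pan-endothelial, arterial, venous, endocardial, brain vascular, hemogenic, erythroid, myeloid, neural, epidermal, mesenchymal or mural and hatching gland cells. Lists for muscle, heart, neural crest, pharyngeal endoderm, pronephros, lens and notochord had too few members measured in the endothelial class to be tested.

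UMI counts were summed per lane over the cells of a class. Genes were tested with edgeR's quasi-likelihood test (TMM scaling, filterByExpr, robust fit) with all 6 lanes in 1 fit, which left 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05, and the number with a fold of at least 1.5 is given beside each count of the main tests. Classes with at least 50 cells in every lane were tested. Arterial cells (29 in the smallest lane), endocardial cells (16), epidermal cells (8) and pharyngeal or gut cells (23) were not. The KO against WT difference in endothelial cells was compared with that in erythroid cells by an interaction term with lane as a block. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, on voom values. The pathway lists were Polycomb repressive complex 1 and 2, Hox clusters, non-Hox developmental transcription factors, Notch, VEGF, BMP and TGF-beta, Wnt, inflammatory and interferon signalling, cell cycle, cytosolic ribosomal proteins, mitochondrially encoded genes, dissociation and immediate-early stress, p53 response and apoptosis, glycolysis and hypoxia, extracellular matrix, flow response, and histone lysine demethylases and COMPASS.

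Shares of cells and shares of cells with a UMI carry exact Clopper-Pearson 95% intervals, which cover counting error only. With 2 lanes against 2 the smallest two-sided exact permutation p is 0.33, so shares were not tested. Cells were thinned to 2000 UMIs before cells with hemogenic transcripts were counted. A count of 0 was read as a limit of 3 counts. The lanes of a genotype were compared with a binomial test per gene (at least 20 UMIs, at least 1.5-fold, adjusted as above). Fold changes of HET and KO share the WT lanes, so 50 simulations of unchanged groups against them were run. For 20330 of the 25108 genes in the files (81.0%), the symbol was found in a gene table of another assembly, GRCz12tu, which was used only to say which genes lie on the chromosome of ezh1.

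Genes named below follow a fixed rule. Besides ezh1 and ezh2, these were the 12 with the largest rise and the 12 with the largest fall in KO against WT endothelial cells, of which 1 is not named, and 6 and 6 in the other comparisons. They had an adjusted p under 0.05, a fold of at least 1.5, at least 10 CPM (counts scaled to the library total) in the higher genotype, and both lanes of one genotype above both lanes of the other. Up to 4 passing members per list and up to 5 genes per other result were added, and gene models without a name were counted but not named. The comparisons, tests, lists and this rule were fixed before the data were examined. On simulated data with the depth of the endothelial lanes, the test found 34.3% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 98.5% of those changed 4-fold, with 9 false calls among 6922 genes. The interaction found 24.6%, 51.6% and 93.5%, with 9 false calls. In both, the changed genes were drawn from those with a mean of at least 10 CPM, so these shares do not cover lower genes. On Poisson draws, which hold counting error only, the lane test found 104 of 200 genes changed 2-fold, with 2 false calls. The real lanes spread more than this, so these draws do not measure its false calls there.

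Alternatives tried were DESeq2's size factors and its Wald test, no low-count filter, the replicate number as a block, leaving out each lane, doublets kept, a stricter cell filter (at least 1000 genes, at most 5% mitochondrial UMIs), and 252 cells of 2000 UMIs per lane. Further ones were Leiden resolution 2, equal cluster makeup in every lane, genes on the chromosome of ezh1 left out, and blood, ribosomal and mitochondrial lists left out. Added after the data had been seen were genes higher in erythroid cells left out, transcripts that differed between lanes left out, a lane score as a covariate, a crossed block, and clustering without the called genes. No genome sequence was used here, so GC content was not tested.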

Results

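Transcripts were counted in single GFP-positive cells from 30 hpf embryos of 3 ezh1 genotypes, with 2 technical lanes each. The series asks how Ezh1 bears on hemogenic fate and on the formation of blood stem and progenitor cells from arterial endothelium. The WT lanes held 31502256 UMIs in 2072 barcodes and 35104900 in 2038. The HET lanes held 28754358 in 1954 and 30284505 in 2057, and the KO lanes 22204794 in 1496 and 23519093 in 1534. After filtering, 10574 cells remained: 1963 and 1933 in WT, 1854 and 1951 in HET, and 1419 and 1454 in KO. Median UMIs per barcode, before filtering, lay between 11457 and 14054.5 in the 6 lanes. Counts of the same gene in the lanes of a genotype spread more than counting error alone gives, with a chi-square per degree of freedom of 22.2 in WT, 11.6 in HET and 24.2 in KO.

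Transcripts of ezh1 were scarce in every genotype and lowest in KO. Over all cells, 21 UMIs were counted in WT (14 and 7 per lane), 11 in HET (5 and 6) and 3 in KO (1 and 2), or 0.336, 0.199 and 0.0697 CPM. The KO to WT ratio was 0.207 with a counting interval of 0.0396 to 0.694, and that of HET to WT was 0.591 (0.257 to 1.28). Without WT replicate 1 the KO to WT ratio was 0.327 and without KO replicate 1 it was 0.267, and in both cases its interval reached 1. In endothelial cells 3 UMIs were found in WT, 1 in HET and 0 in KO, which was too few for a difference to be detectable. A 3' tag reports a mutation only if it lowers the transcript, and the labels do not say whether this one does. ezh2, which encodes the alternative catalytic subunit of the complex, was at 17.8 CPM in WT, 14.7 in HET and 17.9 in KO over all cells, and at 14.9, 15.2 and 14.5 in endothelial cells.

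The sorted cells were a mixture in which endothelium was a minority. Of the 10574 cells, 4726 were erythroid, 1567 endothelial, 1255 neural, 1158 myeloid and 528 mesenchymal or mural, and 920 had no name. Cells without a name were 5.47% of WT, 10.3% of HET and 10.9% of KO cells, which bears on the share of every class. Endothelial cells made up 13.0% of WT cells (11.9 to 14.1%), 13.9% of HET cells (12.8 to 15.04%) and 18.6% of KO cells (17.1 to 20.02%). Both KO lanes (18.3% and 18.8%) lay above both WT lanes (12.9% and 13.0%). The number of endothelial cells was similar, at 253 and 252 in the WT and 259 and 274 in the KO lanes. Erythroid cells numbered 885 and 897 in the WT and 560 and 556 in the KO lanes, and myeloid cells 236 and 259 against 117 and 116. The higher endothelial share in KO thus went mainly with fewer cells of other classes. Erythroid cells were 45.7% of WT cells (44.2 to 47.3%), 48.0% of HET cells (46.4 to 49.6%) and 38.8% of KO cells (37.1 to 40.7%). Myeloid cells were 12.7%, 11.3% and 8.11%, and neural cells 13.1%, 8.91% and 14.2%. The HET and WT lanes lay 2.303 percentage points apart in erythroid cells, a gap of 0.532 under a stricter cell filter, of 1.24 without HET replicate 2 and of 1.64 without WT replicate 1. The GFP gate, which the files do not record, can set such shares. Among cells that were not erythroid, endothelial cells were 23.9% in WT, 26.8% in HET and 30.3% in KO.

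**Figure D1:**
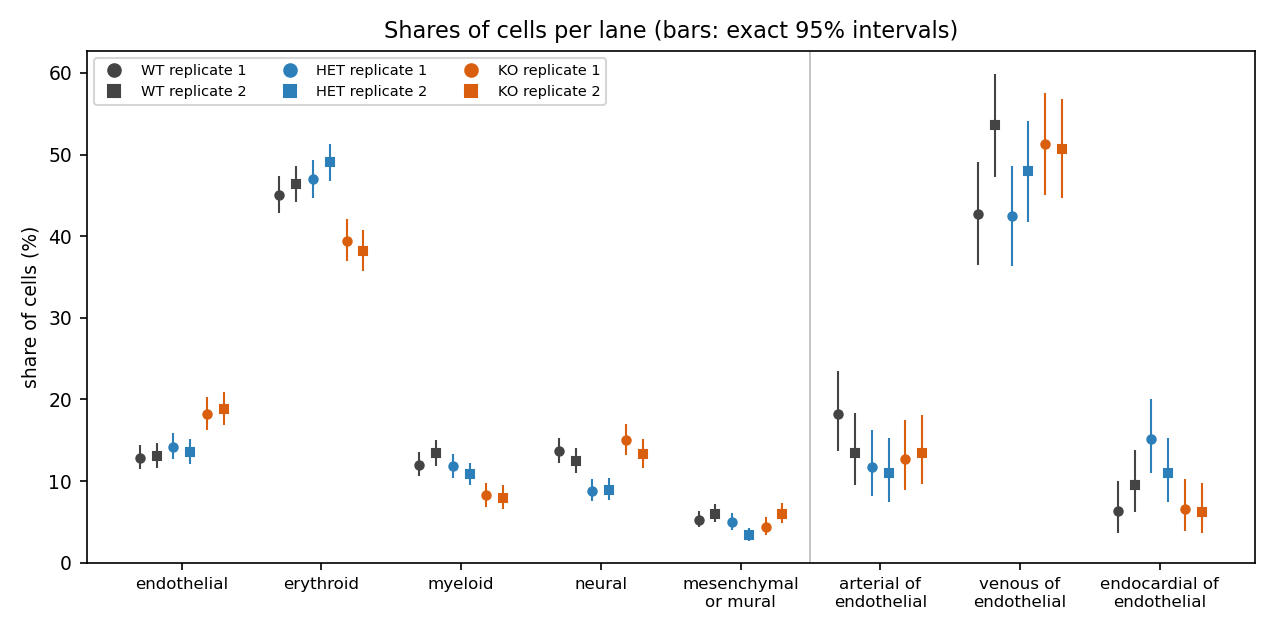
Share of cells per class in each lane, as a percentage of all cells kept (left of the line) or of endothelial cells (right of it), with exact 95% counting intervals. Endothelial cells lie at 12.9% and 13.0% in the WT lanes and at 18.3% and 18.8% in the KO lanes.

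Erythroid cells also differed in their makeup. A cluster led by the anion exchanger gene slc4a1a held 36.0% of WT (33.8 to 38.3%), 37.0% of HET (34.8 to 39.3%) and 20.8% of KO erythroid cells (18.4 to 23.3%). A cluster marked by klf17, a Kruppel-like transcription factor of early blood, held 14.5% in WT (12.9 to 16.3%), 6.78% in HET (5.67 to 8.03%) and 21.1% in KO (18.7 to 23.6%). A cluster without a class name, marked by the pharyngeal transcription factor gene pax1b, was 1.93% of WT cells (1.52 to 2.41%), 6.04% of HET cells (5.31 to 6.85%) and 5.60% of KO cells (4.79 to 6.51%). In each of these 3 clusters the WT and KO lanes did not overlap. Genes that differed between the pools can themselves shift cells across the border of 2 erythroid clusters.

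Within the endothelium the share of arterial cells, from which hemogenic cells arise, overlapped only narrowly between the KO and WT lanes. It did not overlap when cells were clustered again without called genes. Arterial cells were 15.8% of WT endothelial cells (12.8 to 19.3%), 11.3% in HET (8.77 to 14.4%) and 13.1% in KO (10.4 to 16.3%). The WT lanes were at 18.2% and 13.5% and the KO lanes at 12.7% and 13.5%, while both HET lanes (11.7% and 10.9%) lay below both WT lanes. The KO minus WT difference of -2.71 points was -5.05 without WT replicate 2 and -0.359 without WT replicate 1. The HET minus WT difference of -4.50 was -6.84 and -2.15 without the same lanes. Venous cells were 48.1%, 45.2% and 51.0%. Their KO minus WT difference of 2.91 points was -2.54 without WT replicate 1 and 8.34 without WT replicate 2. Their HET minus WT difference of -2.94 points was 2.49 without WT replicate 2, -8.39 without WT replicate 1, -0.194 without HET replicate 1 and -5.69 without HET replicate 2. It moved further still at Leiden resolution 2, where a cluster of 453 endothelial cells was left undivided. Endocardial cells, marked by gata5 and hand2, were 7.92% in WT (5.72 to 10.6%), 13.0% in HET (10.3 to 16.2%) and 6.38% in KO (4.46 to 8.80%). The HET minus WT difference in endocardial cells, 5.12 points, was 3.02 without HET replicate 1. The KO minus WT difference of -1.54 was 0.0549 without WT replicate 2 and -3.14 without WT replicate 1. A further 28.1%, 30.4% and 29.5% could not be assigned to 1 vessel type. When cells were clustered again without the 624 genes that were called or that differed between lanes, arterial shares were 15.2%, 11.7% and 12.7%, endocardial shares 7.72%, 12.6% and 6.15%, and venous shares 64.4%, 64.2% and 67.6%. The arterial shares per lane were then 16.6% and 13.9% in WT and 11.9% and 13.4% in KO. Of the 1567 endothelial cells, 1279 had the same vessel type as before.

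Endothelial cells with transcripts of the hemogenic program were rare in all 3 genotypes. Cells without a class name were not searched, among them a cluster of 59 cells led by spi2 and ighv1-4. At Leiden resolution 2 a cluster of 59 cells with these leading genes also had myb among them. The share of this cluster per genotype is not given here, so a difference in such cells was not assessed. runx1, the transcription factor needed for the emergence of blood stem cells from endothelium, had no UMI in any of 505 WT, 529 HET and 533 KO endothelial cells thinned to 2000 UMIs, nor without thinning. These counts allow a share of cells with a UMI of up to 0.594%, 0.567% and 0.563%. At least 1 UMI of runx1, gata2b, gfi1aa or myb was found in 3 WT cells (0.594%, 0.123 to 1.73%), 1 HET cell (0.189%, 0.00479 to 1.05%) and 2 KO cells (0.375%, 0.0455 to 1.35%). Without WT replicate 2 the WT share was 0%, and without HET replicate 1 the HET share was 0%. Median depths before thinning were 6701, 5365 and 5879 UMIs. At the same thinned depth 5 of 509 WT, 3 of 339 HET and 6 of 407 KO neural cells had such a UMI, and in 4, 3 and 6 of these cells it was one of myb.

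The main comparison asked which genes differed between KO and WT endothelial cells. The embryonic globin transcript hbbe1.1 had the largest fall, from a mean of 1651 CPM in WT to 143 in KO, and other erythroid transcripts fell with it. fus, which encodes an RNA-binding protein, rose from 3.78 to 29.7 CPM, and the crystallin gene crygn2 rose from 49.3 to 151. cst3, which encodes the protease inhibitor cystatin C, fell from 68.8 to 7.73 CPM. The fixed lists of arterial, Notch, hemogenic and pan-endothelial genes held no member that passed the test. In all, 120 of 7187 genes were called, 45 higher and 75 lower in KO, and 102 of them changed at least 1.5-fold; 788 had an unadjusted p under 0.05.

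**Figure D2:**
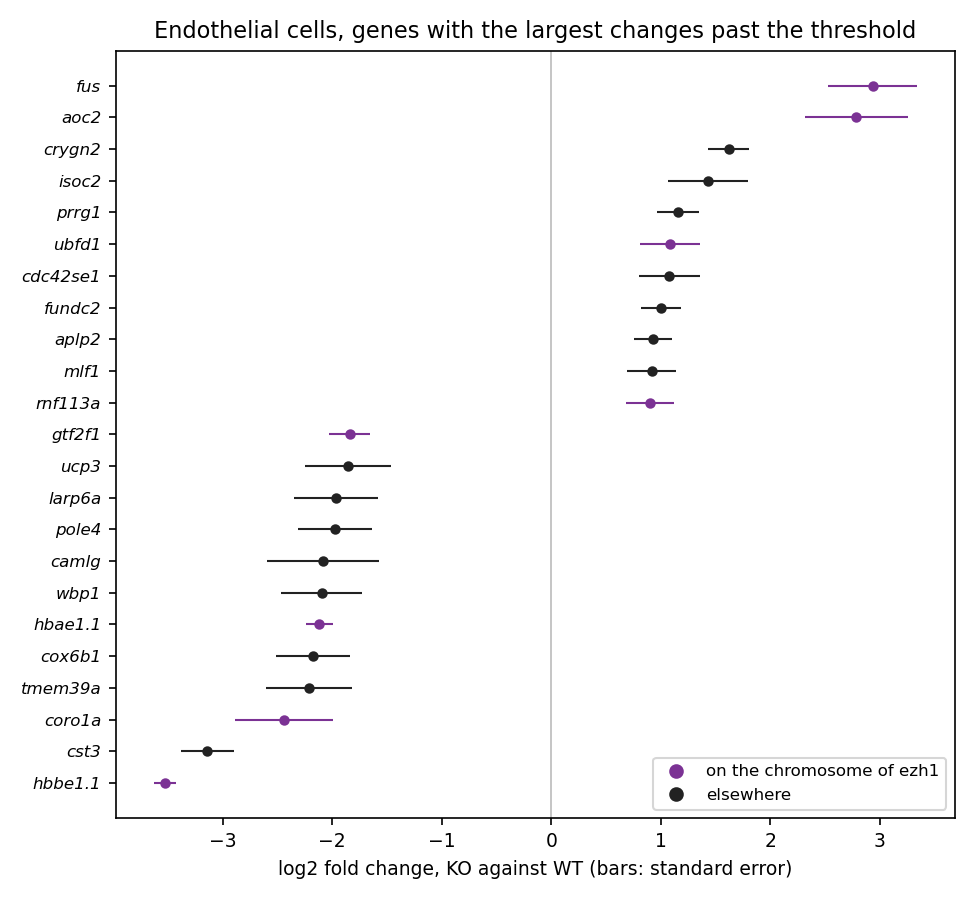
Log2 fold change of KO against WT in endothelial cells for 23 of the 24 genes with the largest changes past the threshold; points are estimates, bars standard errors, and colour marks the chromosome of ezh1. hbbe1.1 lies lowest at -3.53 and fus highest at 2.93.

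Among the 12 largest rises were fus (log2 change 2.93, SE 0.40, adjusted p = 1.24e-04), the copper amine oxidase gene aoc2 (2.79, SE 0.47, adjusted p = 7.09e-04) and crygn2 (1.62, SE 0.19, adjusted p = 3.93e-05), all by edgeR. isoc2 rose by 1.43 (SE 0.37, adjusted p = 0.0374). prrg1, which encodes a membrane protein with a Gla domain, rose by 1.16 (SE 0.19, adjusted p = 4.68e-04), and fundc2, a gene of a mitochondrial outer membrane protein, by 1.01 (SE 0.18, adjusted p = 0.00151). ubfd1 rose by 1.09, cdc42se1 by 1.08, aplp2, a relative of the amyloid precursor protein gene, by 0.93, mlf1 by 0.92 and rnf113a by 0.90, with adjusted p from 0.00176 to 0.0409. HET lay between WT and KO for fus (16.9 CPM) and aoc2 (7.86 CPM), and crygn2 was at 28.0 CPM in HET, below both.

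Among the 12 largest falls, hbbe1.1 changed by -3.53 (SE 0.10, adjusted p = 4.85e-20) and the alpha globin gene hbae1.1 by -2.12 (SE 0.12, adjusted p = 5.77e-08). cst3 changed by -3.14 (SE 0.24, adjusted p = 1.43e-09) and gtf2f1, a gene of the general transcription factor TFIIF, by -1.84 (SE 0.19, adjusted p = 1.90e-07). coro1a, a coronin gene of white blood cells, changed by -2.44 (SE 0.45, adjusted p = 0.00176) from 14.3 to 2.60 CPM. cox6b1, a cytochrome c oxidase subunit gene, changed by -2.18 (SE 0.34, adjusted p = 2.27e-04), tmem39a by -2.21 (SE 0.39, adjusted p = 0.00129) and wbp1 by -2.10 (SE 0.37, adjusted p = 0.00109). camlg changed by -2.08, pole4, an accessory subunit gene of DNA polymerase epsilon, by -1.97, larp6a by -1.96 and the uncoupling protein gene ucp3 by -1.85, with adjusted p from 0.00169 to 0.0365. ucp3 was at 216 CPM in erythroid and 13.2 in endothelial cells, so that, as for globins, free erythroid RNA was not excluded for its fall here and against HET. The hbbe1 copies are nearly identical, so the counting can have split their reads and the size for each is uncertain. Summed over the 3 hbbe1 genes, endothelial cells of KO held 0.435 times the CPM of WT, against 0.0890 times for hbbe1.1 alone. Of all 75 falls, 6 were among the transcripts that differed between the WT lanes in other cells (Fisher odds ratio 6.22, p = 7.13e-04), and these include cst3, camlg, pole4 and larp6a. fus differed between the KO lanes in other cells.

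Of these 24 genes, 9 lie on the chromosome of ezh1, among them fus, aoc2, ubfd1, rnf113a, hbbe1.1, coro1a, hbae1.1 and gtf2f1. With all called genes, 32 of 116 with a known position lie there (27.6%), against 391 of 6908 tested genes (5.66%), a Fisher odds ratio of 6.83 (p = 1.75e-14). Leaving that chromosome out gave 73 calls, and leaving out genes higher in erythroid cells gave 76. Several of the named genes changed in other cells too: fus rose in erythroid (1.55), myeloid (2.00), neural (2.33) and mesenchymal cells (2.74). gtf2f1 fell in erythroid (-0.62), neural (-1.30) and mesenchymal cells (-1.47) and rose in myeloid cells (0.95).

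The count of 120 was 33 with DESeq2's Wald test and 40 with equal cells and UMIs per lane, 187 with no low-count filter, 270 with a block that pairs KO replicate 1 with WT replicate 2 (chosen after the data had been seen), 283 without WT replicate 2 and 237 without KO replicate 2. Without KO replicate 1, a library that differed from its sister lane in abundant transcripts, it was 86, of which 70 were among the 120. Of the genes above, the calls of aplp2 (0.73), camlg (-2.18), isoc2 (1.36), mlf1 (0.73), rnf113a (0.74) and ubfd1 (0.85) ended without that lane. Without KO replicate 2 those of cdc42se1 (0.77) and ucp3 (-1.45) ended, and camlg (-2.09) lost its call without either HET lane. Without WT replicate 1 those of camlg (-1.10), cdc42se1 (0.96), isoc2 (1.08), mlf1 (0.58), ubfd1 (0.97) and ucp3 (-1.51) ended, and without WT replicate 2 that of rnf113a (0.83).

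Of the 30 lists tested, camera called 4 between KO and WT. Erythroid markers fell together: 12 of 14 members fell and all 14 had a negative change, with a median log2 change of -1.25 (camera adjusted p = 4.16e-48; adjusted p = 0.354 with an estimated correlation). Besides hbbe1.1 and hbae1.1, hbae3 changed by -1.50 and hbae1.3 (ENSDARG00000089124) by -1.40; 12 members passed when adjusted over the list alone. Every endothelial cell held globin UMIs. The median per cell, averaged over lanes, was 289.25 in WT, 298.25 in HET and 105.5 in KO, and the KO to WT ratio of 0.365 lay within the 0.311 to 0.383 of 5 other non-erythroid classes.

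**Figure D3:**
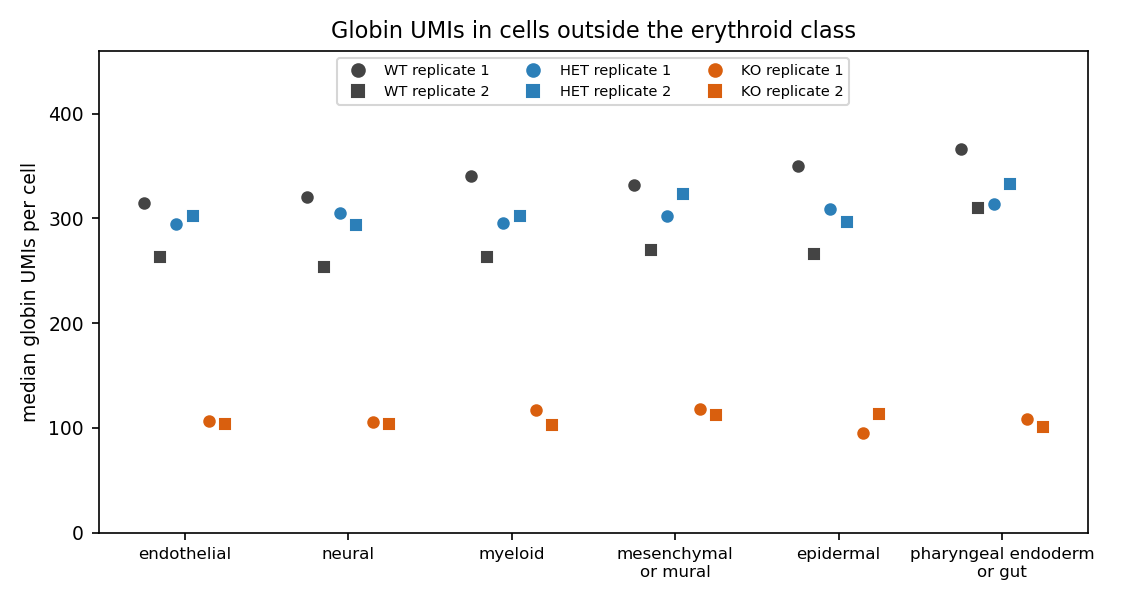
Median globin UMIs per cell in non-erythroid classes, per lane. In endothelial cells the lanes lie at 263.5 and 315 in WT, 294.5 and 302 in HET, and 104 and 107 in KO.

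The other lists called by camera moved little. Of 12 mitochondrially encoded genes, 0 passed edgeR's test over all genes and 2 rose when adjusted over the list alone, with a median of 0.14 (Up, camera adjusted p = 0.00402; adjusted p = 0.597 with an estimated correlation). Of 27 dissociation and stress genes 1 fell, the growth-arrest gene btg2 (-0.65, SE 0.13, adjusted p = 0.00485), and 3 fell when adjusted over the list alone (Down, camera adjusted p = 6.85e-04; adjusted p = 0.559 with an estimated correlation). Of 30 cell cycle genes 0 passed, with a median of -0.14 (Down, camera adjusted p = 0.0267; adjusted p = 0.726 with an estimated correlation). Stress genes such as jun differed between the KO lanes as well, at 267 and 1122 CPM.

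Some pathway genes fell without a camera call for their list. Of 18 BMP and TGF-beta genes, 3 fell: the inhibitor smad7 (-1.77, SE 0.29, adjusted p = 5.41e-04) and the BMP target genes id3 (-0.82, adjusted p = 0.0177) and id1 (-0.40, adjusted p = 0.0225). Of 17 p53 and apoptosis genes, 3 fell: baxb (-1.24, adjusted p = 0.0197) and baxa (ENSDARG00000020623; -0.78, adjusted p = 0.00611), which encode pro-apoptotic proteins, and ccng1 (-0.46, adjusted p = 0.00490), a p53 target. By fry, 0 of 30 lists were called in a direction (lowest adjusted p = 0.0709) and 6 in its mixed test: p53 (adjusted p = 4.84e-04), glycolysis and hypoxia (0.00222), erythroid (0.00526), myeloid (0.00526), BMP and TGF-beta (0.00682) and endocardial (0.0294). The glycolytic aldolase gene aldoaa fell (-0.65, adjusted p = 4.63e-05; 1 of 17 glycolysis and hypoxia genes). klf2a, a gene induced by blood flow, fell (-0.73, adjusted p = 0.00490), which was 1 of 7 flow response and 1 of 5 endocardial genes; adjusted over the list alone, 2 endocardial genes fell. Of 5 myeloid markers, coro1a and the lysozyme gene lyz (-1.58, SE 0.21, adjusted p = 1.67e-05) fell; adjusted over the list alone, 2 rose and 3 fell. In myeloid cells lyz and coro1a were at 49237 and 2282 CPM, against 45.9 and 8.56 in endothelial and 38.6 and 2.90 in neural cells. RNA from myeloid cells, whose share was lower in KO, was thus not excluded for these 2 genes. The calls of baxb (-1.22) and id1 (-0.41) ended without KO replicate 1 and that of id3 (-0.56) without KO replicate 2. Without WT replicate 2 those of baxb (-0.97) and id1 (-0.30) ended, and without either HET lane that of id1 (-0.41).

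The arterial, Notch and hemogenic genes with enough counts to be tested showed no difference that passed. Of 10 arterial genes 0 passed, among them dll4 (-0.18), efnb2a (0.31), hey2 (0.09), cldn5b (0.10), hey1 (-0.53, adjusted p = 0.340) and tbx20 (1.12), and camera gave an adjusted p of 0.986. Of 21 Notch genes 0 passed, with notch1a at -0.33, notch1b at 0.18, her12 at 0.75 (adjusted p = 0.195), her4.1 at 0.38, her9 at 0.40 and lfng at 0.02. Of 3 hemogenic genes measured 0 passed: tal1 at -0.50 (adjusted p = 0.132, and 0.0106 when adjusted over the list alone), lmo2 at -0.08 and cebpa at -0.86. runx1, gata2b, gfi1aa and myb were not among the genes tested, so these 3 say little of the hemogenic program. By the edgeR interaction, the changes of tal1 (difference -0.64, adjusted p = 2.0e-04) and lmo2 (-0.37, adjusted p = 4.2e-04) were lower in endothelial than in erythroid cells. In erythroid cells lmo2 rose by 0.30 (edgeR adjusted p = 0.00311) and tal1 was at 0.14 (edgeR adjusted p = 0.262). Neither gene was thus called lower within endothelial cells. The interaction adjusted neither for free erythroid RNA nor for the makeup of erythroid clusters.

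By edgeR 0 members also passed among 13 pan-endothelial, 7 venous, 4 brain vascular, 7 neural, 6 epidermal, 7 mesenchymal and 3 hatching gland markers. The same held for 9 genes of Polycomb repressive complex 2, 11 of complex 1, 27 Hox genes, 20 other developmental transcription factor genes, 9 VEGF, 12 Wnt and 13 inflammatory genes. It held too for 82 ribosomal protein, 15 extracellular matrix and 17 demethylase and COMPASS genes. Adjusted over the list alone, ecscr rose among the pan-endothelial markers and 1 developmental transcription factor gene rose. Median and mean differed in sign for the pan-endothelial, arterial, endocardial and demethylase lists, and the camera direction for epidermal markers was opposite to both.

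HET and WT endothelial cells differed in more genes than KO and WT. krt94, a keratin gene of the endocardial cluster, rose from 25.3 to 126 CPM and fabp11a, which encodes a fatty acid binding protein, from 191 to 692. pole4 fell from 33.7 to 2.62 CPM and tmem39a from 21.4 to 2.302. In all, 334 genes were called, 131 higher and 203 lower in HET, 233 of them at least 1.5-fold; 1309 had an unadjusted p under 0.05.

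The largest rises by edgeR were krt94 (2.32, SE 0.17, adjusted p = 1.52e-09), fus (2.12, SE 0.46, adjusted p = 0.00738), cst14b.2 (2.07, SE 0.52, adjusted p = 0.0194) and fabp11a (1.86, SE 0.12, adjusted p = 2.91e-09). The membrane protein genes ms4a17a.11 and ms4a17a.9 rose by 1.81 (SE 0.20, adjusted p = 1.05e-06) and 1.72 (SE 0.16, adjusted p = 2.98e-08). The largest falls were pole4 (-3.65, SE 0.45, adjusted p = 2.42e-05), tmem39a (-3.18, SE 0.48, adjusted p = 8.42e-05), wbp1 (-2.72, SE 0.42, adjusted p = 1.31e-04) and C7H11orf68 (-2.55, SE 0.65, adjusted p = 0.0247). qpctla, a gene of the glutaminyl cyclase family, changed by -2.30 (SE 0.58, adjusted p = 0.0350) and the deubiquitinase gene usp2a by -2.30 (SE 0.46, adjusted p = 0.00223). cst14b.2 was at 2571 CPM in myeloid and 4.47 in endothelial cells, so its change need not be one of endothelial cells. pole4, tmem39a and wbp1 also fell in KO. Without HET replicate 1 the calls of fus (1.72), cst14b.2 (1.85), C7H11orf68 (-3.07) and qpctla (-2.98) ended, and without HET replicate 2 those of cst14b.2 (2.26), C7H11orf68 (-2.18), qpctla (-1.86) and usp2a (-2.02). Without WT replicate 1 the call of cst14b.2 (2.02) ended, and without WT replicate 2 that of C7H11orf68 (-2.16).

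The count of 334 was 106 with DESeq2's Wald test, 113 with equal cells and UMIs per lane, 191 with equal cluster makeup and 205 with a lane score as a covariate. It was 96 without HET replicate 1, 140 without HET replicate 2, 579 without WT replicate 2, 566 without KO replicate 2 and 480 without KO replicate 1. Lanes within a genotype differed in abundant transcripts in every class: rps2, a small ribosomal subunit protein gene, was at 8140 and 7234 CPM in the WT, 2660 and 2698 in the HET, and 787 and 5901 in the KO endothelial lanes. Between the KO lanes 69 transcripts differed in cells of the other classes, 66 of them lower in replicate 1; between the WT lanes 109 differed, and between the HET lanes 2.

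**Figure D4:**
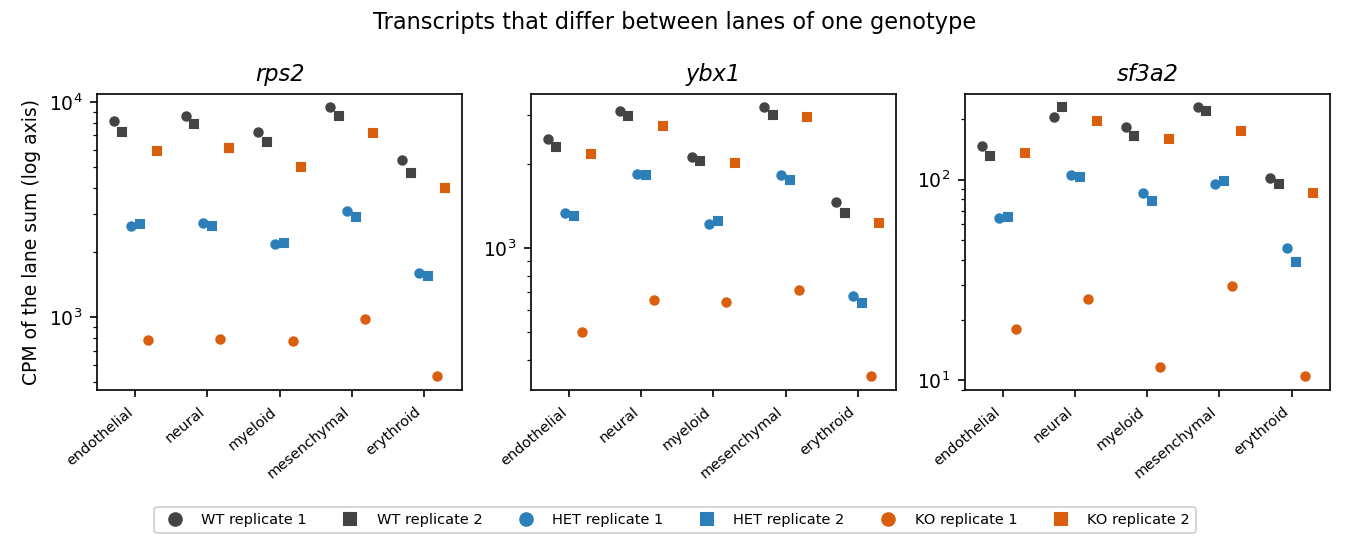
CPM per lane, on a log axis, for rps2, ybx1 and sf3a2 in 5 cell classes. KO replicate 1 lies below KO replicate 2 in every class, by 7.498-fold for rps2 in endothelial cells, and both HET lanes lie between them.

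Camera called 6 lists between HET and WT, and 0 with an estimated correlation; fry called 0 in a direction (lowest adjusted p = 0.0707) and 16 in its mixed test. Of 12 mitochondrially encoded genes 6 rose, among them mt-atp6 (0.84, SE 0.09, adjusted p = 7.77e-07), mt-nd2 (0.63), mt-nd1 (0.54) and mt-cyb (0.46; list Up, camera adjusted p = 7.54e-08; adjusted p = 0.418 with an estimated correlation); 7 rose when adjusted over the list alone. Of 27 Hox genes, which pattern the body axis, 3 fell: hoxd9a (-1.43, SE 0.29, adjusted p = 0.00306), hoxa11b (-0.999, SE 0.21, adjusted p = 0.00484) and hoxb7a (-0.86, SE 0.25, adjusted p = 0.0428). Another 22 had a negative change and 12 fell when adjusted over the list alone (camera adjusted p = 7.18e-07; adjusted p = 0.418 with an estimated correlation). With equal cluster makeup hoxa11b was at 0.10 and the calls of hoxd9a (-0.44) and hoxb7a (-0.05) ended. Without HET replicate 1 the calls of hoxa11b (-0.76), hoxb7a (-0.50) and mt-cyb (0.45) ended, without HET replicate 2 those of hoxd9a (-1.10), mt-nd1 (0.48) and mt-cyb (0.47), and without WT replicate 2 that of hoxb7a (-0.63).

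Of 27 dissociation and stress genes, 6 fell and 1 rose. The immediate-early genes junbb (-0.92, adjusted p = 0.0304), ier2a (-0.75, adjusted p = 8.64e-04) and atf3 (-0.73, adjusted p = 2.78e-04) fell with btg2 (-0.72, adjusted p = 0.00101), while the heat shock gene hsp70.1 rose (0.50, adjusted p = 7.67e-04). The list was called Down (camera adjusted p = 1.37e-05; adjusted p = 0.418 with an estimated correlation), and 7 fell when adjusted over the list alone. Of 14 erythroid markers 6 rose and 1 fell: hbae1.3 (ENSDARG00000088330; 0.65), hbbe1.3 (0.62) and hbbe1.2 (0.55) rose and hbbe1.1 fell (-0.74, adjusted p = 5.10e-06), whereas the sum of the 3 hbbe1 genes was 1.41 times that in WT. Median globin UMIs per endothelial cell in HET were 1.03 times those in WT, while median UMIs per endothelial cell were lower (5533.5 and 5208 in the HET, 6870 and 6562 in the WT lanes), so the rise in CPM goes with fewer other UMIs per cell. That list was called Up (camera adjusted p = 3.10e-05; adjusted p = 0.560 with an estimated correlation), and 7 rose and 1 fell when adjusted over the list alone. Of 17 glycolysis and hypoxia genes 4 fell: aldocb (-1.97), pgk1 (-1.41, adjusted p = 9.70e-04), egln3 (-1.09) and aldoaa (-0.56; camera adjusted p = 0.0268; adjusted p = 0.418 with an estimated correlation). Of 17 p53 genes ccng1 fell (-0.67, adjusted p = 4.33e-05; camera adjusted p = 0.0314; adjusted p = 0.418 with an estimated correlation). Without HET replicate 1 the calls of junbb (-0.85), hbae1.3 (0.62), hbbe1.2 (0.53), aldocb (-1.73) and egln3 (-1.26) ended. Without HET replicate 2 those of junbb (-0.98) and egln3 (-0.93) ended, and without WT replicate 2 those of junbb (-0.72) and egln3 (-0.89). Without WT replicate 1 camera called 10 lists.

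Single members of other lists changed between HET and WT. With equal cluster makeup, 16 of the 53 named calls between HET and WT ended and 2 reversed. Of 13 pan-endothelial genes 2 fell, ecscr (-1.56, adjusted p = 0.00185) and etv2 (-0.42, adjusted p = 0.00685), an ETS factor gene of early endothelium. Of 7 venous genes dab2 fell (-0.53, adjusted p = 3.75e-04). Of 5 endocardial genes gata5 rose (1.15, adjusted p = 9.05e-04) and aqp8a.1 fell (-0.67, adjusted p = 2.78e-04); with equal cluster makeup gata5 was at 0.37 and aqp8a.1 at 0.11, and neither passed. Among 20 developmental transcription factor genes gata5 rose, and gata2a (-1.58, adjusted p = 0.00738), an endothelial and hematopoietic factor gene, and foxd2 (-0.86, adjusted p = 0.0251) fell. Of 18 BMP and TGF-beta genes smad7 (-1.49, adjusted p = 0.00194) and id1 (-0.67, adjusted p = 6.60e-05) fell and id2b rose (0.80, adjusted p = 0.0445). Of 13 inflammatory genes the chemokine gene cxcl12b (-1.93, adjusted p = 1.86e-05) and tnfrsf1a (-1.47, adjusted p = 0.0342) fell. Of 21 Notch and 7 neural genes her4.2 (ENSDARG00000056729), a Notch target, rose (0.92, adjusted p = 0.0337). Of 30 cell cycle genes tyms (0.75, adjusted p = 0.0179) and pcna (0.38, adjusted p = 0.00952) rose and cdc20 (-0.60, adjusted p = 0.0428) fell. Of 15 matrix genes col18a1a rose (1.09, adjusted p = 0.00912), and postnb (-0.45, adjusted p = 0.0263) and col5a1 (-1.06, adjusted p = 0.0494) fell; these 2 are also among the 7 mesenchymal markers. Of 5 myeloid markers srgn rose (0.34, adjusted p = 0.0420), and of 6 epidermal markers krt4 fell (-1.13, adjusted p = 0.0468). Without HET replicate 1 the calls of ecscr (-1.56), etv2 (-0.30), dab2 (-0.51), gata5 (0.97), gata2a (-1.44), foxd2 (-0.89), id2b (0.50), her4.2 (0.75), tyms (0.57), pcna (0.38), cdc20 (-0.46), postnb (-0.26), col5a1 (-0.76), srgn (0.24) and krt4 (-1.32) ended. Without HET replicate 2 those of gata2a (-1.72), foxd2 (-0.83), tnfrsf1a (-0.80), her4.2 (1.08), pcna (0.38), cdc20 (-0.73), col18a1a (1.01), col5a1 (-1.41), srgn (0.44) and krt4 (-0.96) ended. Without WT replicate 1 those of id2b (0.50), cdc20 (-0.41), col5a1 (-0.93), srgn (0.35) and krt4 (-1.09) ended, and without WT replicate 2 those of her4.2 (0.76), tyms (0.56), postnb (-0.33) and srgn (0.33).

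By edgeR 0 members passed between HET and WT among 10 arterial, 3 hemogenic, 4 brain vascular and 3 hatching gland genes, 9 of Polycomb repressive complex 2, 11 of complex 1, 9 VEGF, 12 Wnt, 82 ribosomal protein, 7 flow response and 17 demethylase and COMPASS genes. Adjusted over the list alone, 1 arterial gene rose and 1 fell, 2 brain vascular genes rose and 1 fell, 1 complex 1 gene rose, and 1 hemogenic, 1 hatching gland and 2 Wnt genes fell. Median and mean differed in sign for the arterial, complex 1, transcription factor, matrix and flow lists, and the camera direction for myeloid and hatching gland markers was opposite to both.

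KO and HET endothelial cells differed in 211 genes, 121 higher and 90 lower in KO, of which 163 changed at least 1.5-fold; 1070 had an unadjusted p under 0.05. ecscr, which encodes an endothelial surface protein, was at 11.5 CPM in HET and 56.3 in KO, and crygn2 at 28.0 and 151. The largest rises by edgeR were usp2a (2.72, SE 0.43, adjusted p = 1.55e-04), crygn2 (2.42, SE 0.21, adjusted p = 4.91e-07), ecscr (2.29, SE 0.28, adjusted p = 6.54e-06), commd1 (2.099, SE 0.48, adjusted p = 0.0329), the otolith matrix gene stm (1.99, SE 0.46, adjusted p = 0.0116) and amh (1.71, SE 0.39, adjusted p = 0.0102), which encodes anti-Mullerian hormone. cst14b.2 had no UMI in either KO lane and was at least 13.1-fold lower there, with 3 counts over the group as the floor (adjusted p = 6.50e-05). It also fell in myeloid (-1.99) and erythroid cells (-4.07), and RNA from myeloid cells was not excluded for it here either. Also lower in KO were hbbe1.1 (-2.79, SE 0.10, adjusted p = 1.67e-17), hbae1.1 (-2.07, SE 0.12, adjusted p = 4.53e-08), cox6b1 (-2.16, SE 0.35, adjusted p = 1.63e-04), cst3 (-2.07, SE 0.28, adjusted p = 1.38e-05) and ucp3 (-2.06, SE 0.39, adjusted p = 0.00163). The count of 211 was 87 with DESeq2's Wald test, 95 with equal cells and UMIs, 99 with equal cluster makeup and 328 with the lane score. It was 78 without HET replicate 1, 117 without HET replicate 2, 403 without WT replicate 1, 391 without WT replicate 2 and 204 without KO replicate 1. Calls that ended were those of amh (1.98), commd1 (2.05), stm (1.25) and ucp3 (-1.87) without HET replicate 1, amh (1.48) and commd1 (2.13) without HET replicate 2, commd1 (1.69) without KO replicate 1 and amh (1.36) without KO replicate 2.

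Over all cells, where differences in cell makeup add to those within classes, 1125 of 13336 genes differed between KO and WT, 518 higher and 607 lower, 638 of them at least 1.5-fold. hbbe1.1 (-2.66, SE 0.10, adjusted p = 1.41e-06), grna (-2.63), a granulin gene, and ighv1-4 (ENSDARG00000096355; -4.85, adjusted p = 7.98e-05), an immunoglobulin gene, fell. mlf1 (1.65) and the Notch target her15.2 (0.98, adjusted p = 5.98e-05) rose. The symbol ighv1-4 is also a leading gene of a cluster of 59 cells without a class name. A different number of those cells was not excluded for the fall of ighv1-4. Of the 120 endothelial calls, 64 were also called here, 63 in the same direction. Between HET and WT 677 genes were called, 338 higher and 339 lower, 396 of them at least 1.5-fold, among them commd1 (-3.00), hbbe1.1 (-1.55), atf3 (-1.07), pax1b (1.60) and ociad2 (1.22). The KO against WT count was 589 without KO replicate 1, 678 without HET replicate 1, 670 without HET replicate 2, 732 with DESeq2's Wald test and 448 with equal cells and UMIs per lane.

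Other cell classes differed between KO and WT as well. Each of these classes holds several clusters, and equal cluster makeup was tried in the endothelium only. A different makeup within a class was thus not excluded. Neural cells had 107 called genes (62 higher, 45 lower, 90 at least 1.5-fold), among them hbbe2 (-1.56), hbbe1.1 (-3.42), hbae3 (-1.35), hbae1.1 (-2.04) and her15.2 (0.87). Myeloid cells had 225 (79 higher, 146 lower, 151 at least 1.5-fold), with hbbe1.1 (-3.78), ighv1-4 (-5.55), hbae1.1 (-2.33), hbae1.3 (-1.58) and hbbe3 (-1.36). RNA from the unnamed cluster of 59 cells led by spi2 and ighv1-4 was not excluded for ighv1-4 here. Mesenchymal cells had 75 (33 higher, 42 lower, all at least 1.5-fold), with the galectin gene lgals1l1 (5.52) and loxl5b, which had no UMI in either WT lane, higher, and hbbe2 (-1.65), hbae1.3 (-1.96) and the fibromodulin gene fmoda (-1.12) lower. Erythroid cells had 582 (319 higher, 263 lower, 276 at least 1.5-fold): hbbe1.1 (-2.43) and lyz (-1.37) fell, and mlf1 (2.40), hspbp1 (1.08) and the kinase gene sgk2a (1.07) rose. The level of lyz in erythroid cells, 47.7 CPM, was close to that in endothelial and neural cells, so RNA from myeloid cells was not excluded there either. In erythroid cells hbbe1.1 was at 26441 CPM in WT, 7297 in HET and 4534 in KO, whereas the sum of the 3 hbbe1 genes in KO was 1.103 times that in WT. Of endothelial calls tested in both classes, 41 of 96 were also called in neural cells (1.48 for independent lists), 47 of 104 in myeloid (2.75), 25 of 91 in mesenchymal (0.883) and 50 of 102 in erythroid cells (7.93). The direction was the same for 39 of the 41, 44 of the 47, 25 of the 25 and 42 of the 50. All classes come from the same 6 libraries, so differences between lanes and free RNA enter each list, and independent lists are no measure of chance here.

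Within the endothelium, venous cells had 47 genes called between KO and WT (18 higher, 29 lower, 41 at least 1.5-fold) and undivided cells 45 (9 higher, 36 lower, 43 at least 1.5-fold). In venous cells hbbe1.1 (-3.66), cst3 (-3.25), hbbe1.2 (-1.23) and the apolipoprotein E gene apoeb (-1.17, adjusted p = 9.70e-07) fell and crygn2 rose (1.63). In undivided cells the 5 leading genes were globins, from hbbe1.1 (-3.26) to hbbe1.2 (-1.14). Between HET and WT, 345 genes were called in venous and 75 in undivided cells, 270 and 68 of them at least 1.5-fold; in venous cells stmn1a, a tubulin regulator gene, rose (1.51) and apoeb (-1.43), the clotting factor gene f13a1b (-1.15), dnase1l4.1 (-1.05) and hbbe1.1 (-0.93) fell. In undivided cells mt-atp6 (0.97), ms4a17a.9 (1.41), hbae1.3 (0.93), hbbe1.3 (0.89) and mt-nd2 (0.86) rose.

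Between HET and WT, 1416 genes were called in erythroid cells (740 higher, 676 lower), 578 in myeloid, 145 in neural and 36 in mesenchymal cells, of which 542, 359, 111 and 34 changed at least 1.5-fold. commd1 fell in erythroid (-3.31) and myeloid cells (-2.55). In erythroid cells unc119a (2.47) and cmtm7 (1.16) rose and hbbe1.1 (-1.54) and serinc5 (-1.39) fell. In myeloid cells the granule genes cpa5 (0.92) and npsn (0.72) rose and marcksl1b (-1.21) and hbbe1.1 (-1.41) fell. cpa5 and npsn are leading genes of a myeloid cluster of 319 cells. Equal cluster makeup was not tried in these classes, so a different makeup within them was not excluded. In neural cells the forebrain factor genes dlx5a (2.01) and otpb (1.297) rose with abhd6a (1.101) and her15.2 (0.82), and atf3 (-1.95) fell. In mesenchymal cells dlx4a rose (3.13) and junba (-2.15), anxa11b (-1.93), C7H11orf68 (-3.53) and igfbp1a (-3.80) fell.

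The KO against WT counts in these classes depended on single lanes. Without KO replicate 1 there were 271 in erythroid and 113 in myeloid cells. Without WT replicate 2 there were 961 in erythroid, 191 in neural, 141 in mesenchymal and 120 in venous cells. In venous cells there were also 97 without HET replicate 1, 98 without HET replicate 2 and 133 without KO replicate 2, and in undivided cells 71 without KO replicate 2.

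For 162 of 10602 genes, the KO against WT change in endothelial cells differed from that in erythroid cells (edgeR interaction with lane as a block), 55 with a higher and 107 with a lower change in endothelial cells; 116 of the differences were at least 1.5-fold. hbbe2 changed by -1.32 in endothelial and by 0.31 in erythroid cells, a difference of -1.63 (SE 0.09, adjusted p = 1.44e-64). blvrb, which encodes biliverdin reductase B, changed by -1.31 and 0.15. The ferritin gene fthl27 (ENSDARG00000031776) changed by 0.37 and -0.57, icn by -0.40 and 0.68, and tmsb4x, a gene of the actin-binding protein thymosin beta 4, by 0.34 and -0.26. On their own, the changes of icn in endothelial cells (adjusted p = 0.654) and of tmsb4x in endothelial (adjusted p = 0.181) and erythroid cells (adjusted p = 0.307) were not called. Globin counts in endothelial cells include RNA that is free in the droplets, so that of hbbe2 need not be the endothelial cells' own. The same limit holds for blvrb, at 910 and 973 CPM in the erythroid and 106 and 91.6 in the endothelial WT lanes. In the erythroid WT lanes icn was at 83.4 and 100.2 CPM and tmsb4x at 95.3 and 95.7. In the endothelial WT lanes they were at 788 and 1147.5 and at 9155 and 11685.5. Free RNA from other cells was thus not excluded for their erythroid changes. The test did not adjust for the makeup of erythroid clusters. The count was 75 without KO replicate 2 and 92 without WT replicate 2.

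HET and KO changes in endothelial cells were compared across 7187 genes, which are not independent replicates. Both rose in 14 genes and both fell in 28, with opposite calls in 8. Unchanged groups gave 0.22, 0.28 and 0.02 on average in simulations where both comparisons shared the simulated WT lanes. These simulations had few calls to share, on average 1.52 higher and 1.40 lower in KO and 0.92 higher and 1.08 lower in HET. Their shared calls were thus bound to lie near 0 and are no measure for the observed ones. Independent lists of these sizes would share 0.820 and 2.12. The correlation of log2 changes was 0.508, against 0.482 in the simulations (SD 0.0116, highest 0.511), and the covariance was 0.116 against 0.0536, a difference of 0.0621. The correlation was 0.489 among genes above 50 CPM, where the simulations gave 0.485. The simulated lanes had a single spread per gene, fitted over all lanes. The correlation was within what shared WT lanes of this spread give. The covariance was above the highest simulated value (0.0605). The simulations do not hold the deviations of the real WT lanes. Nor do they hold a difference peculiar to the WT pool, which would enter both changes alike and which these lanes cannot show.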

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

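The interaction test was fixed beforehand, whereas the tests of explanations below were chosen only after the results they measure had been seen.

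The KO against WT change differed between endothelial and erythroid cells for 162 genes by the interaction test. The difference, endothelial minus erythroid, was -1.63 for hbbe2, -1.46 for blvrb, -1.06 for icn, 0.95 for fthl27 (ENSDARG00000031776) and 0.62 for tmsb4x. hbbe2 and blvrb are more abundant in erythroid cells, so free erythroid RNA was not excluded for them. icn and tmsb4x are more abundant in endothelial cells, so free RNA was not excluded for their erythroid values. The different makeup of erythroid clusters was not adjusted for.

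Erythroid transcripts were lower in KO than in WT endothelial cells. If droplets holding 2 cells were the source, cells with little globin would be alike in both genotypes, but the KO to WT ratio at the 10th percentile of globin UMIs was 0.286, with 56 at most in a KO lane and 159.1 at least in a WT lane. A change of these genes within endothelial cells alone is argued against as well: the median change of 13 members was -1.29 there, -1.16 in neural, -1.21 in myeloid and -1.85 in mesenchymal cells, and endothelial cells differed from these by a median of 0.168 (SD 0.158). RNA released from erythroid cells into all droplets may account for the pattern, since the ratio of median globin UMIs, 0.365, lay within the 0.311 to 0.383 of 5 other classes. Why less of it was present in the KO lanes stays open, including the different number of erythroid cells and any effect of the genotype on them, which was not tested.

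Many transcripts were lower in HET than in WT endothelial cells. With equal cluster makeup, the median log2 change of 202 of the 203 transcripts was -0.67 (SD over genes 0.65) in place of -0.86, and 198 stayed negative. The calls of only 103 were kept, at a median SE of 0.18 in place of 0.19. For these 103 a different makeup of clusters within the endothelium is argued against as the whole cause. For the rest it stays open, because all 203 were chosen as lower in these same cells, which favours negative values. A shift between libraries that follows no genotype may contribute: relative to other genes, these transcripts were lower in KO replicate 1 than in replicate 2 by a median of -0.17 in neural (158 genes), -0.08 in myeloid (158 genes) and -0.13 in mesenchymal cells (153 genes). Only 1 of the 203 was among the transcripts that differed between the KO lanes (Fisher odds ratio 0.511) but 13 among those that differed between the WT lanes (Fisher odds ratio 5.18), so these account for few of the calls. All lanes share a fit, so a transcript unlike between the KO lanes has a large spread and is seldom called. Of 65 transcripts lower in KO replicate 1 in other cells, 55 were lower in HET than in WT endothelial cells, with a median log2 change of -0.355. The lower number of ezh1 copies cannot be told apart from such a shift, because each genotype has its own libraries; of 203 transcripts called lower in HET, 28 were called lower in KO too and 173 had a negative KO change.

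Genes called between KO and WT lay on the chromosome of ezh1 more often than other tested genes. Free erythroid RNA is argued against, although globin genes lie there, because the odds ratio was 6.22 without the genes higher in erythroid cells. Loss of ezh1 acting on genes wherever they lie would favour no chromosome. The highest odds ratio on any other of the 25 was 3.10 in endothelial cells without the erythroid list. No interval was computed for it, so calls may be uneven over other chromosomes too. Variants inherited together with the mutant allele are a candidate explanation. Without the erythroid list the odds ratio for the ezh1 chromosome was 5.69 (3.58 to 9.03) in endothelial cells, with 25 of 104 called genes there. In the other classes it lay between 3.05 and 5.10, but these come from the same libraries and are not separate support. Nearness of the called genes to ezh1 along the chromosome was not examined here. In HET, with 1 mutant copy, it was 1.65 (1.097 to 2.48) in endothelial, 1.14 (0.552 to 2.34) in neural, 1.31 (0.933 to 1.85) in myeloid, 1.57 (1.26 to 1.97) in erythroid and 3.18 (1.21 to 8.31) in mesenchymal cells, and which called genes on that chromosome respond to ezh1 itself stays open.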

How the results depend on the processing

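The lane score, the crossed block, leaving out genes higher in erythroid cells or transcripts that differed between lanes, clustering without called genes, the left-out lanes for ezh1, hemogenic cells and the correlation, and the replicate block for the correlation were tests chosen after the data had been seen. Where 1 lane is left out, the lone lane of its genotype is assumed to vary like the others. For endothelial named genes, 1716 of 1970 combinations of gene and setting kept direction and call, 252 kept direction only and 2 reversed. DESeq2's Wald test ended 25 of 36 such calls in KO against WT and 22 of 51 in HET against WT, and equal cells and UMIs 18 of 29 and 21 of 45. Over all cells 130 of 130, in other classes 418 of 420 and for the interaction 34 of 35 were kept. With equal cluster makeup 16 of 53 such calls between HET and WT ended, and aqp8a.1 and hoxa11b reversed, to 0.11 and 0.10. In KO against WT, fus, crygn2, hbbe1.1, cst3, hbae1.1, hbae3 and aldoaa kept their calls in every setting that tested them.

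DESeq2's Wald test gave 33, 106 and 87 endothelial genes in KO against WT, HET against WT and KO against HET, in place of 120, 334 and 211, and 732 over all cells in place of 1125. Of its 33 calls 21.2% were higher, against 37.5%. Equal cells and UMIs per lane gave 40, 113, 95 and 448, with 25.0% of the 40 higher; fewer counts were tested. No low-count filter gave 187 in KO against WT, leaving out the ezh1 chromosome 73 and genes higher in erythroid cells 76, both with fewer genes tested. Equal cluster makeup gave 191 in HET against WT and 99 in KO against HET, and the lane score 205 and 328. For the Wald test, the makeup and the lane score the cause was not tested. An estimated correlation left 0 lists called by camera in place of 4 and 6. Leiden resolution 2 chose the same endothelial cells, so it tested nothing there.

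Leaving out 1 lane gave 86 to 283 genes in KO against WT, 96 to 579 in HET against WT, 78 to 403 in KO against HET and 589 to 1057 over all cells. KO against WT it gave 271 to 961 in erythroid, 113 to 303 in myeloid, 84 to 191 in neural, 70 to 141 in mesenchymal, 48 to 133 in venous and 31 to 71 in undivided cells, and 75 to 157 for the interaction. Lists called in HET against WT were 6 to 10, the correlation of HET and KO changes 0.421 to 0.654, and the ezh1 ratio 0.143 to 0.327. Shares with a hemogenic UMI were 0 to 1.19% in WT and 0 to 0.379% in HET. WT had 0 such cells at 1000 UMIs, and HET and KO had 0 with 2 UMIs required. The strict cell filter moved share differences to 1.46 (endothelial, HET minus WT), 0.532 (erythroid, HET minus WT) and -4.76 (erythroid, KO minus WT). Clustering without called genes moved the neural HET minus WT difference to -2.93, and resolution 2 the venous one to -11.98; the cause was not tested.

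The replicate numbers were treated as labels, since deviations of same-numbered endothelial lanes correlated at 0.0402, -0.159 and -0.0678 (WT with HET, WT with KO, HET with KO) and those over all cells at 0.350, -0.380 and -0.126, with no common sign. With the replicate number as a block the counts were 114, 273 and 159, 792 over all cells, 483 erythroid, 269 myeloid, 105 neural, 64 mesenchymal, 51 venous and 33 undivided, with 5 and 6 lists called and a correlation of 0.508. Under this block 8 of 53 named endothelial calls ended in HET against WT and 1 of 36 in KO against WT. The crossed block, KO replicate 1 with WT replicate 2, gave 270 in KO against WT. At the depth of these lanes most 1.5-fold changes would be missed, and ezh1 and the hemogenic genes were near the floor.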

Other observations

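Small clusters of further cell types, named here from their markers only, were present in the sort. A skeletal muscle cluster marked by actc1b and mylz3 was 0.693% of WT cells (0.457 to 1.01%), 0.263% of HET cells (0.126 to 0.483%) and 1.01% of KO cells (0.677 to 1.45%). A cluster of pancreatic endocrine cells marked by ins and gcga was 0.308%, 0.210% and 0.104%, with overlapping intervals. Ciliated cells marked by foxj1a were 0.231%, 0.0788% and 0.522% (9, 3 and 15 cells), and cells of the ear marked by stm and oc90 were 0.128%, 0.131% and 0.418% (5, 5 and 12 cells). Epidermal cells were 1.87% in WT (1.47 to 2.35%), 0.894% in HET (0.620 to 1.25%) and 2.23% in KO (1.72 to 2.84%), but the 2 HET lanes differed, with 26 of 1854 and 8 of 1951 cells. These shares were not tested.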
